A study of Homo sapiens with 7 samples.

How the data were processed

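Expression was measured with Affymetrix 3' expression arrays on total RNA from 5 leukemia cell lines under 0.1% DMSO and from U937 cells after 12 h and 24 h with Tan IIA at 3 µg/mL, with 1 array for each of the 7 conditions. The deposited values are log2 expression per probe set, and the submitters' processing notes name Affymetrix Expression Console 1.1 and RMA, which corrects background, quantile-normalises the arrays and summarises each probe set. Other settings upstream are not given in the sources used here. The table held 54675 probe sets and 7 columns, and their quantiles were checked to be nearly equal, with the largest gap to the mean quantile at 0.15 in log2.

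Probe sets were named with a table of gene symbols and identifiers made for the platform. It listed 42898 probe sets, of which 41097 had 1 gene and 1801 had several. A further 11777 were not listed. Symbols were updated to the current RefSeq symbol through the gene identifier for 41043 probe sets. The annotation of the platform is old, so a symbol can differ from what a probe set detects. Each of 19775 genes was represented by the probe set with the highest mean over the 7 arrays among those with 1 gene. The 62 Affymetrix control probe sets were described apart. Some items are not reported here.

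No test was possible, since no group had a second array, and differences of log2 values were described. A gene was counted in a comparison if its higher value reached 5.45, the median of all probe sets over the 7 arrays, and it was called higher or lower from a 2-fold difference. A gene was set apart in a line if it lay at least 2-fold above the highest or below the lowest of the other 4 lines. The 12 h and 24 h lists share 1 DMSO array, so their overlap and covariance were compared with 100 simulations of arrays with no effect and a shared control. The noise of these was drawn from the difference between the treated arrays, which counts any real change between 12 h and 24 h as noise.

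There were 34 fixed gene lists, 24 of pathways and 10 of cell types and reference genes. For each, the median log2 change, its interquartile range and the members past 2-fold were taken, with its percentile among 10000 random lists matched on mean expression in 20 bins. Lines were compared by list as each line minus the mean of the other lines. The lists, the filter, the size threshold, the rule for named genes and a first set of other settings were fixed before the data were examined.

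Named genes were the 10 largest increases and the 10 largest decreases against DMSO at each time, and the 5 largest each way between 24 h and 12 h. Every other probe set of a named gene that passed the filter had to move in the same direction. For the lines, they were the 10 genes with the largest margin above and the 10 below all other lines in U937, and the 3 largest above in each other line. From each list, up to 4 counted members with the largest changes were open to be named, and a short set that included CCL2, CYP3A4, CYP1A1, HMOX1, NQO1, CDKN1A, DDIT3, MYC, BCL2 and ABCB1 was named always. For the lines this list rule was applied to the difference from the mean of the other lines.

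The settings fixed in advance were the mean of all probe sets of a gene, leaving out probe sets open to cross-hybridisation (names ending in _x_at), no filter, a filter at the 75th percentile, a filter at the 95th percentile of genes not expressed in blood cells (7.09), a 1.5-fold threshold, centring on the median change, cyclic loess between arrays, and leaving out each other line. After the data had been seen, scaling on the median of the poly-A spike controls, counting only genes whose probe sets moved in 1 direction, and then scaling on the mean of the poly-A spikes were added. The last was added after the results of the first were known. Setting every value under the filter to the filter was added later still, with all other results known. It gives lower bounds where the lower value of a named gene was under the filter.

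The steps were tested on simulated data made from the U937 arrays. All 50 genes raised by 2 in log2, all 50 lowered by 2, all 50 raised by 1.5 and all 50 lowered by 1.5 were recovered. These changes lie well past the 2-fold threshold, so their recovery says nothing about genes closer to it. Smaller changes of single genes were not tried, although the genes called at 12 h had median changes of 1.23 and −1.13. Of 12453 unchanged genes, 7 passed 2-fold (0.056%). A list raised by 0.3 lay at percentile 100, and 1 of 100 unchanged lists lay outside the 1st to 99th percentile. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, figures matplotlib 3.10.9, and cyclic loess limma 3.58.1 in R 4.3.3. The number of arrays limits the precision.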

Results

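Gene expression was measured in 5 human leukemia cell lines on 7 Affymetrix arrays of 54675 probe sets, with 1 array for each condition. HL60 (promyelocytic), MEG01 (megakaryoblastic), MOLT (T lymphoblastic), THP1 (monocytic) and U937 (monocytic) cells were profiled under the vehicle, 0.1% DMSO. U937 cells were also profiled after 12 h and 24 h with tanshinone IIA (Tan IIA), a diterpene quinone of the Salvia miltiorrhiza root, at 3 µg/mL. All cells had been cultured for 24 h beforehand, and the length of the DMSO treatment was not given. Values were log2 RMA expression, and the 7 arrays had medians between 5.44 and 5.47. Because no condition was repeated, no difference could be held against the spread between replicates, and no p-value was computed. Genes were counted as higher or lower when they differed at least 2-fold, and the number of arrays limits the precision of every value.

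The first comparison asked which genes differed in U937 cells after 12 h of Tan IIA. CCL2, a chemokine that attracts monocytes, was 8.34-fold lower (log2 change −3.06). CXCL8, which attracts neutrophils, was at −2.06 on its brighter probe set, of a kind open to cross-hybridisation, and at least 2.43-fold lower on its other one, which fell under the filter on low values, 5.45, and is set to it here (−1.49 as read). GPR84, a receptor for medium-chain fatty acids on myeloid cells, changed by −1.64, and the collagenase gene MMP1 by −1.26. The D-type cyclin gene CCND2 was lower by a log2 change of −1.23 (−0.58 on another probe set), and INSIG1, a sterol sensor of the endoplasmic reticulum, by −1.28. On the other side, TXNIP, which binds thioredoxin and restrains glucose uptake, was 3.52-fold higher (1.82). ARRDC3, another alpha-arrestin gene, went from 4.18 to 6.85 (2.67). Its DMSO value lay under the filter, so only a bound of at least 2.63-fold holds when values under the filter are set to it.

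The rest of the 10 largest increases at 12 h covered several functions. They were the membrane protein gene MS4A4A (1.49), the ribosomal RNA precursor RNA45SN5 (1.45), TUFT1 (1.36), TMT1A (1.31, but 0.13 on another probe set), the endotoxin co-receptor gene LY96 (1.28), the OX40 ligand gene TNFSF4 (1.27), SMIM14 (1.26) and the uridine phosphorylase gene UPP1 (1.24). The remaining large decreases were in the long noncoding RNA CCDC26 (−1.70), the G protein subunit gene GNAL (−1.52), the mucin gene MUC19 (−1.30) and FGFBP3 (−1.15). In all, 22 of 12625 counted genes were at least 2-fold higher and 27 at least 2-fold lower (0.388% together). Where a gene among these had other probe sets above the filter, 27 of 28 of those moved in the same direction. Of the 20 named genes, 9 (ARRDC3, MS4A4A, TUFT1, LY96, TNFSF4, CCDC26, GNAL, MUC19 and MMP1) stayed on both arrays under 7.09, the 95th percentile of genes not expressed in blood cells. In 7 of the 20 the lower value was under the filter, and with such values set to it 17 of the 20, all but LY96, GNAL and MMP1, were still at least 2-fold changed.

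Genes of ribosome assembly and of sterol synthesis were lower together at 12 h. Of 24 counted genes in the list of MYC and ribosome biogenesis, 22 were below 0, with a median of −0.45, and none reached 2-fold. MYC itself, a transcription factor of cell growth, changed by −0.72, RRP9 by −0.72, LYAR by −0.66 and PES1 by −0.61. Of 22 genes of cholesterol synthesis and its regulator SREBP2, 19 were below 0 (median −0.39), among them HMGCS1 (−0.91), MSMO1 (−0.86) and DHCR7 (−0.84). Neither median was reached by any of 10000 random lists of the same size and expression level.

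Targets of the stress regulators ATF4 and NRF2 lay on the other side, whereas the list of the heat shock response did not. Of 28 genes of ATF4 and the unfolded protein response, 22 were above 0 at 12 h (median 0.26, although just below 0 when arrays were scaled on the mean of their poly-A spikes). Its members with the largest changes were the mTOR inhibitor gene DDIT4 (1.23), the asparagine synthetase gene ASNS (0.98), the CHOP gene DDIT3 (0.91) and the serine synthesis gene PHGDH (0.88). Of 20 targets of the oxidative stress regulator NRF2, 17 were above 0 (median 0.11, and below 0 under both poly-A scalings). The cystine transporter gene SLC7A11 (0.87), NQO1 (0.79), PGD (0.66) and HMOX1 (0.64) had the largest values among them.

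Cell cycle genes parted by phase at 12 h. Of 31 genes of G1/S and DNA replication, 30 were below 0 (median −0.18), led by the flap endonuclease gene FEN1 (−0.50), CCNE1 (−0.50) and MCM4 (−0.46). Of 36 mitotic genes, 28 were above 0 (median 0.25, and below 0 when scaled on the mean of the poly-A spikes), with CENPA at 0.52, CDC25C at 0.51 and KIF20A at 0.43. The list of CDK inhibitors and D cyclins had a median of 0.22, also below 0 under that scaling. It held CCNG2 (1.17, but 0.23 on a dimmer probe set) and KLF4 (0.46) beside TXNIP and CCND2. In the lysosome and phagosome list, 21 of 31 genes were above 0 (median 0.16, and below 0 under both poly-A scalings), including GRN (0.65), NPC2 (0.60) and CLN3 (0.57). Interleukin and growth factor receptors had a median of 0.12, below 0 under both poly-A scalings, with IL10RA at 0.60 and TNFRSF1B at −0.62.

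Directions of small changes depended on what the arrays were scaled to. In the U937 arrays the poly-A spikes, transcripts added to each RNA sample before labelling, read 0.27 higher at 12 h and 0.22 higher at 24 h than under DMSO. Hybridisation spikes, which are added after labelling, also read higher, by 0.14 and 0.12. The poly-A readings need not reflect the RNA samples alone, therefore. Scaling on the median of the poly-A spikes moved the median of all counted genes to −0.20 at 12 h and −0.26 at 24 h. With their mean the shifts were −0.27 and −0.21. The 22 higher and 27 lower genes at 12 h became 14 and 78 under the first scaling and 8 and 118 under the second. List medians are therefore given relative to the deposited scale, on which the median gene changed by 0.00 at 12 h and 0.02 at 24 h.

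The second comparison asked what differed after 24 h of Tan IIA. CCL2 was 12.5-fold lower than under DMSO (log2 change −3.64), and CXCL8 was at −2.67 on its brighter probe set and, as at 12 h, under the filter on its other one (−1.68 as read, at least 2.43-fold lower). CCDC26 (−2.31) and MMP1 (−2.20) fell under the filter, which leaves at least 2.58-fold for CCDC26 and no 2-fold change for MMP1. The growth-induced transcription factor gene EGR1 changed by −1.84, GPR84 by −1.79, the adhesion molecule gene CEACAM6 by −1.66, and QPCTL, which encodes a glutaminyl cyclase, by −1.52. TXNIP was 4.04-fold higher (2.02, but 1.94-fold on a dimmer probe set). ARRDC3, under the filter in DMSO, was at least 3.54-fold higher (3.10 as read). CCNG2, an atypical cyclin of arrested cells, was 3.22-fold higher (1.58-fold on a dimmer probe set). C5AR1, the receptor of complement fragment C5a, was at 1.69 as read, from a DMSO value under the filter. TSC22D3, known as a glucocorticoid-induced gene, was higher by 1.63 (0.44 on another, dimmer probe set), the ATP-gated channel gene P2RX7 by 1.57, the B cell linker gene BLNK by 1.57 and the autophagy receptor gene OPTN by 1.54.

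SMIM14 (1.55) completed the 10 largest increases together with DDIT4 (1.58), and GNAL (−1.54) and MUC19 (−1.49) completed the decreases. At this time 63 of 12593 counted genes were at least 2-fold higher and 36 at least 2-fold lower (0.786% together). These became 23 and 147 when scaled on the median of the poly-A spikes, and 26 and 123 with their mean. Of the other probe sets of these genes, 58 of 63 moved in the same direction. HINT3 (−2.57) and GNL3L (−2.02), singled out after their values were seen, were left out of the named genes because a further probe set of each moved the opposite way. Of the 20 named genes, C5AR1, CCDC26, MMP1, GNAL, QPCTL and MUC19 stayed under 7.09 on both arrays, and 17 of the 20 were still 2-fold changed with values under the filter set to it, all but C5AR1, GNAL and MMP1.

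**Figure D1:**
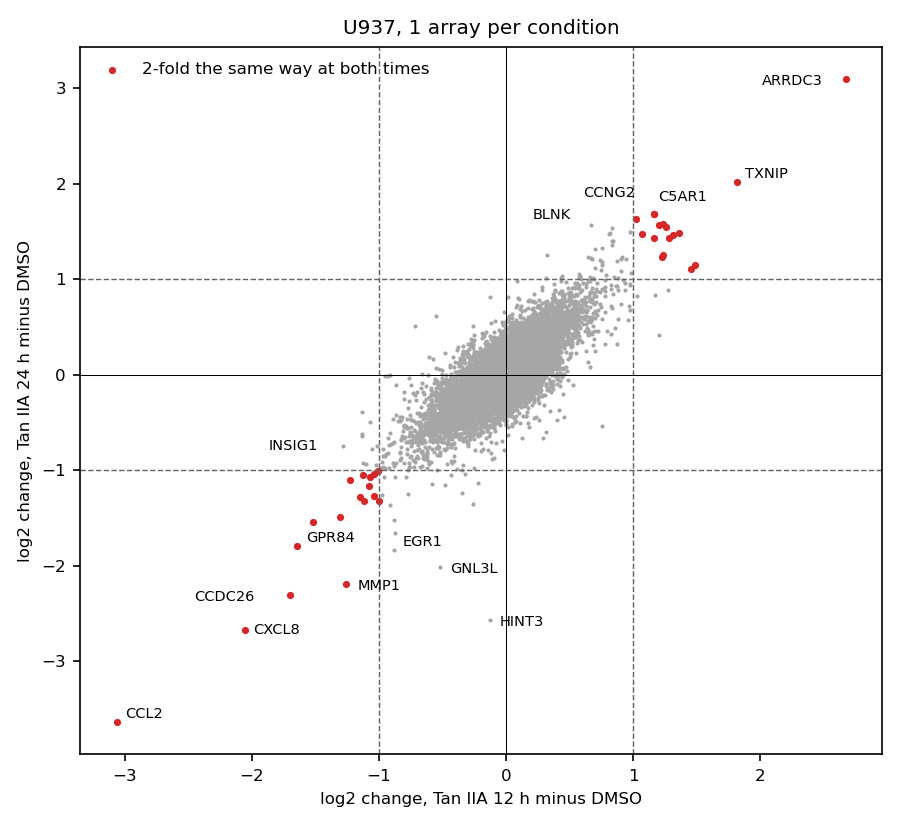
Log2 change of each counted gene in U937 cells after 12 h (horizontal) and 24 h (vertical) of Tan IIA against the same DMSO array, with dashed lines at 2-fold. Red points are the 34 genes at least 2-fold changed the same way at both times, from CCL2 (−3.06 and −3.64) to ARRDC3 (2.67 and 3.10).

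All 24 counted genes of MYC and ribosome biogenesis were below 0 at 24 h, with a median of −0.42. MYC changed by −0.96, the ribosome assembly factor gene MRTO4 by −0.94, LYAR by −0.80 and RRP9 by −0.79. Ribosomal protein genes did not follow: 16 of 21 were above 0, with a median of 0.06 that lay below 0 under both poly-A scalings. Of the sterol genes, 15 of 22 were still below 0 (median −0.16). DHCR7 was at −0.82, INSIG1 at −0.74 and the fatty acid enzyme gene SCD at −0.48, while HMGCS1 was at 0.00.

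The chemokine list had 10 of 14 counted genes below 0 at 24 h (median −0.23), with CCR2 at −0.58 and the fractalkine receptor gene CX3CR1 at 0.58. NF-kB targets had 14 of 23 below 0 (median −0.13), among them BCL2A1 (−0.64) and RELB (−0.54). CCL2 and CXCL8 belong to both lists and were the members past 2-fold in each. The granulocyte and promyelocyte list had 10 of 13 genes below 0 (median −0.37). Its largest changes were in FUT4 (−0.88), the proteinase gene PRTN3 (−0.80), PRG2 (−0.66) and the granulocyte transcription factor gene CEBPE (0.58). Monocyte and macrophage markers split evenly, with 7 of 16 above 0 and 8 below, and a median of 0.00. C5AR1 was the single member past 2-fold.

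NRF2 targets were higher together at 24 h, with 17 of 20 above 0 and a median of 0.30. HMOX1, the heme oxygenase gene, was at 1.23 and NQO1 at 1.05, and SLC7A11 (0.94) and BLVRB (0.88) followed. In the list of ATF4 and the unfolded protein response, 4 genes were at least 2-fold higher and 1 at least 2-fold lower. DDIT4, the stress-induced SESN2 (1.40), DDIT3 (1.21) and ATF3 (1.20) were higher, whereas the chaperone cofactor gene SDF2L1, named after its value was seen, was lower at −1.16. The median of all 28 genes in this list was 0.28, and just below 0 when scaled on the median of the poly-A spikes.

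All 36 mitotic genes were above 0 at 24 h (median 0.26, and below 0 when scaled on the median of the poly-A spikes), with CKAP2 at 0.58, CDC25C at 0.56, NEK2 at 0.55 and UBE2C at 0.47. Of the 31 G1/S genes, 25 were below 0 (median −0.11, at percentile 1.07 and so inside the range of random lists), led by E2F1 (−0.48) and MCM4 (−0.47). The list of CDK inhibitors and D cyclins had 15 of 16 genes above 0 and a median of 0.50, with KLF6 at 0.85. Conversely, CCND2 was at −1.10 (−0.80 on another probe set). Autophagy genes had 13 of 17 above 0 (median 0.26, and below 0 when scaled on the median of the poly-A spikes), with WIPI1 (0.91) and NBR1 (0.55) behind OPTN. Lysosome and phagosome genes had a median of 0.16 and oxidative phosphorylation genes 0.11, and both were below 0 under both poly-A scalings. ATP6V0D1 (0.73) and SDHC (0.48) had the largest changes in these.

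**Figure D2:**
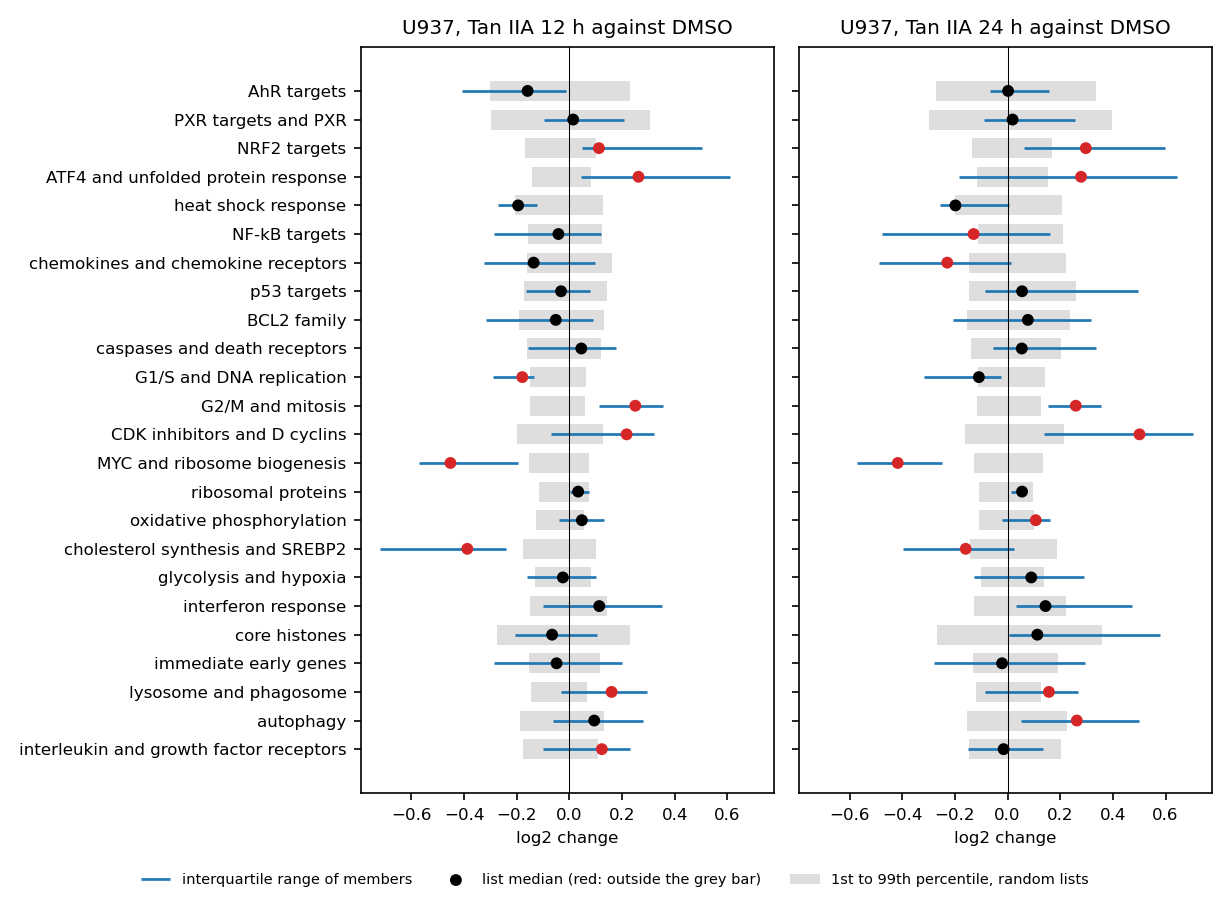
Median log2 change (points) and interquartile range (lines) of each pathway list in U937 cells after 12 h and 24 h of Tan IIA, with grey bars for the 1st to 99th percentile of matched random lists and red points outside them. The ribosome biogenesis list lay lowest (−0.45 and −0.42), and each median above 0, except those of NRF2 targets and of CDK inhibitors and D cyclins at 24 h, was below 0 under at least 1 poly-A scaling.

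Of the 34 lists, 9 had a median outside the 1st to 99th percentile of matched random lists at 12 h and 12 at 24 h, where 0.68 would fall by chance if lists behaved as random draws. Genes of a list are not independent, so these percentiles describe the arrays and are not tests. The lists inside that range at both times had medians between −0.20 and 0.14, and every one of those medians above 0 was below 0 under both poly-A scalings. The medians of AhR and PXR targets and housekeeping genes at 24 h, and of glycolysis and T cell genes at 12 h, also changed sign with median centring or cyclic loess. Medians at 12 h and 24 h were −0.16 and 0.00 for AhR targets, 0.01 and 0.02 for PXR targets, −0.20 and −0.20 for the heat shock response, and −0.03 and 0.06 for p53 targets. They were −0.05 and 0.08 for the BCL2 family, 0.05 and 0.05 for caspases and death receptors, −0.03 and 0.09 for glycolysis and hypoxia, and 0.11 and 0.14 for the interferon response. Core histones were at −0.07 and 0.11, and immediate early genes at −0.05 and −0.02. Among the other cell types, medians were 0.08 and 0.14 for megakaryocyte, 0.09 and −0.04 for erythroid, 0.00 and −0.01 for T cell, 0.08 and −0.11 for B cell, 0.05 and −0.09 for natural killer cell and −0.15 and −0.06 for stem and progenitor markers. Housekeeping genes had medians of 0.03 and 0.00, and genes not expressed in blood cells 0.04 and 0.09.

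Single genes stood out within these quiet lists. CYP1A1, the main drug-metabolising target of AhR, was at −0.89 and −0.93, whereas the heme synthesis gene ALAS1 was at 0.78 and 0.83. CYP3A4, the main target of PXR, was at 0.01 and −0.03 (0.31 at 12 h on another probe set, and −0.19 at 12 h when scaled on the median of the poly-A spikes). Its probe set is open to cross-hybridisation and read between 7.36 and 7.56 in all 5 lines. The others read at most 5.80 in U937. In U937 under DMSO, 4 of 10 measured genes of the PXR list were above the filter. Whether PXR targets responded therefore cannot be read from CYP3A4. The mitophagy receptor gene BNIP3L was at 0.68 and 1.22, and BCL2A1, an NF-kB target that blocks apoptosis, was at −1.13 at 12 h. BCL2 itself was at 0.12 and 0.32, but its 4 probe sets disagreed, from −0.10 to 0.12 at 12 h and from −0.30 to 0.32 at 24 h, so its direction is open. The p21 gene CDKN1A was at 0.26 (just below 0 when scaled on the mean of the poly-A spikes) and 0.50. The interferon-induced IFIT3 was at 0.81 and 1.47, and the histone gene H2BC21 at 1.16 at 24 h. The drug efflux gene ABCB1 was below the filter in U937 cells, at 3.37 under DMSO.

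**Figure D3:**
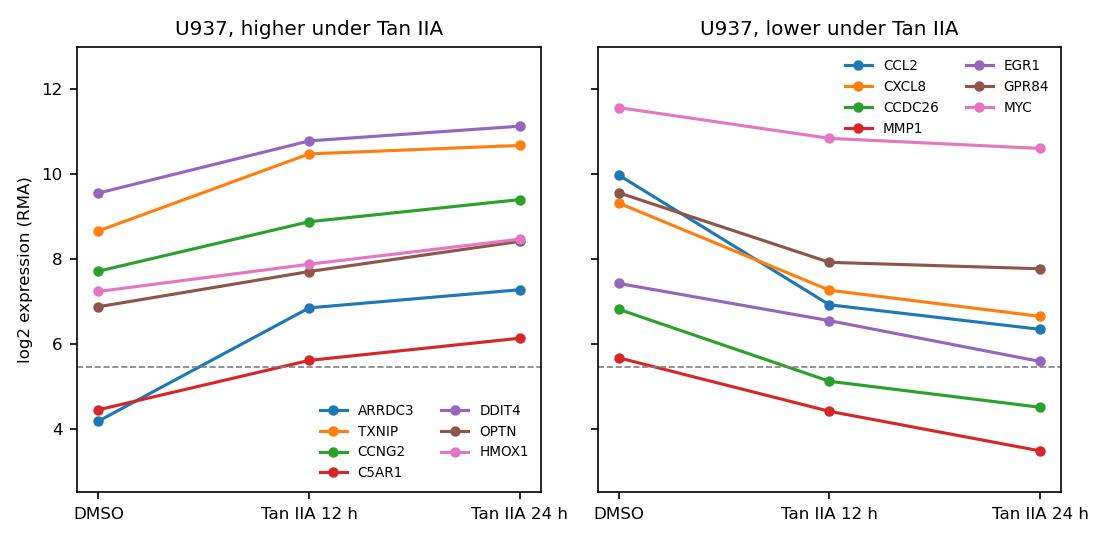
Log2 RMA expression of 14 genes on the 3 U937 arrays, 1 point per array, with the filter on low values as a dashed line. CCL2 went from 9.98 under DMSO to 6.92 and 6.34 under Tan IIA, and ARRDC3 from 4.18 to 6.85 and 7.28.

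Both times were compared with the same DMSO array, so their overlap was set beside that of simulated arrays with no effect and 1 shared control. At both times 17 genes were at least 2-fold higher, 17 were at least 2-fold lower, and 0 were changed 2-fold in opposite directions. The simulated overlaps averaged 0.88 and 0.73 genes and reached at most 5 and 3 in 100 simulations. The covariance of the 12 h and 24 h changes across 12477 genes was 0.0657, against 0.0203 in simulated arrays. Pearson's r across genes was 0.79, against 0.50 in those simulations, and genes are not independent replicates. With the mean of all probe sets of a gene the overlap was 10 higher and 11 lower genes, it was 14 and 14 with values under the filter set to it, and 8 and 52 when scaled on the median of the poly-A spikes. How much of the overlap beyond the simulations comes from the shared DMSO array was not measured.

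The third comparison, between the treated U937 arrays, did not use the DMSO array. EGR1 was lower at 24 h than at 12 h (−0.96), as was the endoplasmic reticulum chaperone gene HSP90B1 (−0.96). Both were short of 2-fold. Of 22 sterol genes, 17 were above 0 (median 0.15), but at percentile 97.67 this median lay inside the range of random lists. Among them were HMGCS1 (0.91), MSMO1 (0.76), IDI1 (0.62) and STARD4 (0.56). All 16 genes of CDK inhibitors and D cyclins were above 0 (median 0.23), including KLF6 (0.62) and CCNG2 (0.52), as were 16 of 17 BCL2 family genes (median 0.25), with BNIP3L at 0.54 and BAK1 at 0.37. Chemokine genes were lower, with 11 of 13 below 0 (median −0.17), and so were granulocyte genes, with 11 of 13 below 0 (median −0.18) and PRTN3 at −0.61.

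Few genes differed 2-fold between 12 h and 24 h: 4 of 12642 counted genes were higher and 5 were lower. Of the other probe sets of these 9 genes, only 5 of 9 moved in the same direction, and of the 5 lower genes 2 had no disagreeing probe set. The higher ones were the noncoding RNA LINC01119 (1.23), ANKDD1A (1.17), the chloride transporter gene SLC12A5 (1.07) and EMP1 (1.06), with TAF7L just short of 2-fold (0.998). ZNF765 (−1.30) and the phosphorylase kinase gene PHKA1 (−1.17) were lower. The other 3, HINT3 (−2.44), GNL3L (−1.49) and the replication gene GINS4 (−1.09), are named here after their values were seen. PPP1R16B was the remaining named decrease, at −0.94. Of the 10 named genes, 8, all but ZNF765 and HSP90B1, stayed under 7.09 on both arrays. The 4 and 5 genes became 2 and 4 with values under the filter set to it, and 2 and 9 when scaled on the median of the poly-A spikes. Outside the 1st to 99th percentile lay 11 list medians, among them ATF4 and the unfolded protein response (−0.02, and above 0 when scaled on the mean of those spikes).

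The fourth comparison asked how the 5 lines differed under DMSO, since the series was built to find genes related to Tan IIA sensitivity. The labels give no sensitivity for any line, so each line was compared with the others. U937 cells stood apart in single transcripts in both directions. The myeloid receptor gene CD93 was 27.7-fold above the highest of the other 4 lines. For most genes named here the lower value was under the filter, so folds are lower bounds with such values set to it, and their order is not read. The type IV collagen gene COL4A2 was at least 46.1-fold above the other lines and the anion transporter gene SLC26A9 at least 41.8-fold. The heparan sulfate enzyme gene HS3ST2 was 28.3-fold above, and SLAMF8 13.3-fold, over values above the filter but under 7.09. COX8C was at least 11.3-fold above, and SEPTIN10, ST6GALNAC3, SH3RF3 and ART3 between at least 2.66-fold and at least 7.15-fold. Conversely, the chromatin protein gene HMGN3 was at least 128-fold below the lowest other line, SDCBP at least 40.0-fold and the tetraspanin gene CD81 at least 35.4-fold. REEP3, NRIP1, GGH, HNRNPLL, SEPTIN11, BIVM and CD84 were at least 6.73-fold to 13.9-fold below.

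Lineage markers set MOLT and MEG01 apart, whereas HL60 and THP1 overlapped in part. Differences from the mean of the other lines are given as read, and where those lines were under the filter, as for RAG1 in MOLT, their size is limited by background signal. In MOLT, 26 of 27 T cell markers were at least 2-fold above the mean of the other lines (median 5.33), among them DNTT (8.22), BCL11B (7.60), RAG1 (7.30) and LCK (7.14). In MEG01, the same held for 13 of 16 megakaryocyte markers (median 3.26), including ARHGAP6 (6.97) and the integrin gene ITGA2B (6.61), and for 10 of 12 erythroid markers (median 3.18), including CA1 (7.10) and HBZ (5.38). In HL60, 18 of 21 granulocyte markers were at least 2-fold higher (median 3.09), led by the myeloperoxidase gene MPO (8.83) and PRG2 (6.54), and 12 of 20 monocyte markers (median 1.52), led by S100A8 (6.43) and CD14 (5.29). THP1 had 12 of 20 monocyte markers at least 2-fold higher (median 1.57), with S100A8 at 4.69 and ITGAM at 3.76, and 11 of 21 granulocyte markers (median 1.53). Of the 12 monocyte markers in each of HL60 and THP1, 7 were the same genes, and CD14 was at −0.51 in THP1. With values under the filter set to it, the medians were 4.89 for T cell markers in MOLT, 2.96 and 3.18 for megakaryocyte and erythroid markers in MEG01, 2.64 and 1.04 for granulocyte and monocyte markers in HL60, and 0.97 and 0.86 for monocyte and granulocyte markers in THP1. All of these medians kept their sign under every scaling tried.

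Granulocyte markers split in U937 cells, whereas lysosome and chemokine genes were higher. Of 21 granulocyte markers, 11 were at least 2-fold above the mean of the other lines and 6 at least 2-fold below (median 1.06). The largest were ELANE (4.68), RNASE2 (4.15), PRTN3 (4.15) and AZU1 (3.58). These do not set U937 apart from the other myeloid lines. ELANE, PRTN3 and AZU1 read as high or higher in HL60 and THP1, and RNASE2 read higher in THP1. The differences come mainly from MEG01 and MOLT, where these genes read under the filter. Monocyte and macrophage markers were not high in U937 as a list. Their median difference was 0.11, and −0.155 with values under the filter set to it. Their median level was 6.28 in U937, 7.04 in HL60 and 7.16 in THP1. Lysosome genes had 16 of 31 members 2-fold higher (median 1.01), including CTSD (2.70), NPC1 (2.51) and CTSZ (2.38). NF-kB targets (median 0.86) and chemokine genes (median 0.86) were higher as well, at 0.67 and 0.47 with values under the filter set to it. The chemokine median did not set U937 apart from the other myeloid lines. It was 0.78 in HL60 and 0.66 in THP1, or 0.58 and 0.59 with values under the filter set to it. In U937, BCL2A1 was at 5.33, CCL2 at 4.95, CCL5 at 3.91 and CXCL8 at 3.20. CCL2 read 9.98 in U937, 8.19 in HL60, 4.35 in THP1, 3.80 in MEG01 and 3.79 in MOLT, whereas CXCL8 read higher in HL60 (10.62) than in U937 (9.32). The decreases under Tan IIA and these line differences share the same U937 DMSO array, so that genes with large decreases tend to read high here.

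Genes of MYC and ribosome biogenesis were high and interferon genes low in U937. Of 24 genes of MYC and ribosome biogenesis, 23 were above the mean of the other lines (median 0.67), including RRP12 (1.47) and LYAR (1.41). MYC itself was not high in U937. It read 11.57 there, 12.51 in HL60, 12.15 in MOLT, 11.515 in MEG01 and 10.18 in THP1. Medians were 0.44 for G1/S genes and 0.45 for mitotic genes, but these did not set U937 apart. The median level of G1/S genes was 10.6 in U937, 10.7 in HL60, 10.9 in MOLT, 10.4 in THP1 and 9.2 in MEG01. That of mitotic genes was 10.32 in U937 and 10.31 in THP1. The interferon list had 9 of 27 genes at least 2-fold lower (median −0.74), with XAF1 at −3.86 and IFI44 at −3.36. The list of CDK inhibitors and D cyclins had a median of −0.34. It was −0.18 with values under the filter set to it, and 0.21 when scaled on the median of the poly-A spikes. TXNIP was at −3.31, CCND2 at 2.10 and CDKN2A at 4.63. CCND2 read 10.875 in U937, below HL60 (11.04) and MEG01 (11.50) and above MOLT (7.62) and THP1 (4.92). Apart from the list of CDK inhibitors and D cyclins, the medians in this paragraph kept their sign under every scaling. In other lines, interferon genes were low in HL60 (−0.72) and high in MOLT (0.95) and THP1 (0.57, or 0.29 with values under the filter set to it), core histones were high in MEG01 (2.67), and lysosome genes were low in MOLT (−1.33).

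**Figure D4:**
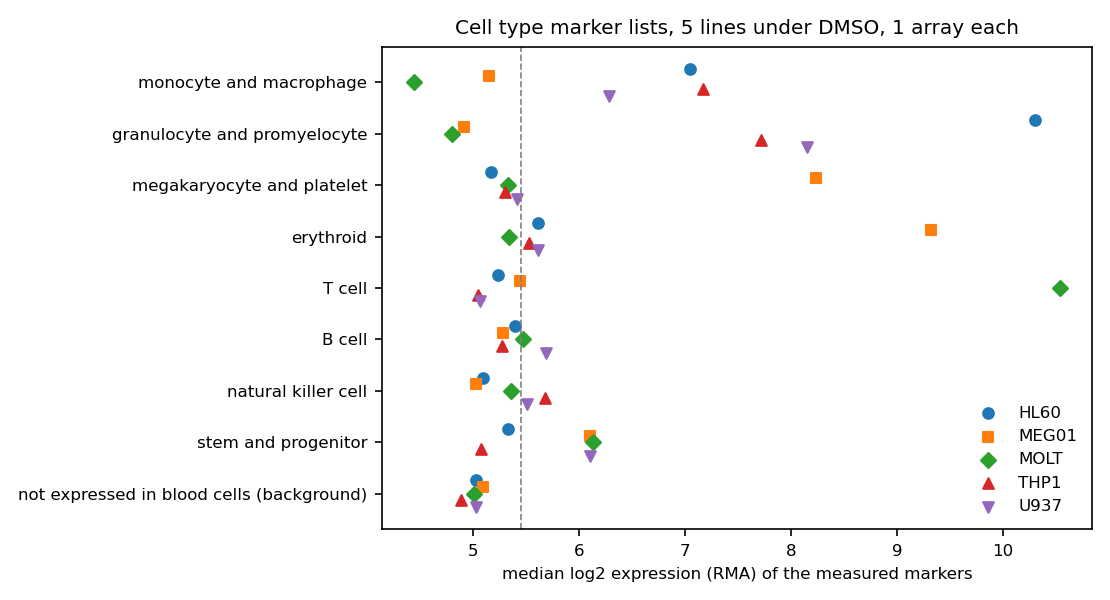
Median log2 RMA expression of the measured markers of each cell type list in the 5 lines under DMSO, 1 array per line, with the filter on low values as a dashed line. T cell markers stood highest in MOLT, megakaryocyte and erythroid markers in MEG01, and granulocyte markers in HL60, each on the deposited scale and under every scaling tried.

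Between pairs of lines, 1312 genes were at least 2-fold higher and 959 lower in U937 than in HL60, of 13022 counted. The numbers were 2115 and 2089 of 13460 against MEG01, 1926 and 1787 of 13232 against MOLT, and 1463 and 1597 of 13194 against THP1. Of 14288 genes counted across the lines, 268 were set apart at least 2-fold above all others in U937 and 211 below. Without the HL60 line they were 415 and 373, and 688 and 118 when scaled on the median of the poly-A spikes. HL60 had 152 above and 212 below, MEG01 861 and 468, MOLT 574 and 504, and THP1 472 and 181. In HL60, MPO was 183-fold and FGL2 32.6-fold above the nearest line, which read under 7.09, and CEACAM8 at least 5.83-fold. The nearest line was under the filter for all 9 genes named in the other lines, so these are bounds with such values set to it. They were at least 69.4-fold for NPY1R, 67.9-fold for MAGEA6 and 33.9-fold for GNG11 in MEG01, at least 189-fold for DNTT, 72.2-fold for BCL11B and 31.2-fold for RAG1 in MOLT, and at least 21.7-fold for TWIST1, 13.3-fold for ADGRL2 and 10.9-fold for TSPYL5 in THP1. These are margins to the nearest line, whereas the list values are differences from the mean, as read.

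Poly-A spikes read lower in U937 than in every other line, by −0.99 against MEG01 and −0.23 against THP1 at the extremes. Hybridisation spikes also read lower in U937 against HL60 (−0.24), MOLT (−0.22) and THP1 (−0.17), but hardly against MEG01 (−0.01). Scaling on the median of the poly-A spikes put the median gene of U937 0.54 above the mean of the other lines. That of THP1 was 0.28 above, that of MOLT at −0.28 and that of MEG01 at −0.68. The 1312 and 959 genes against HL60 then became 2446 and 569, those against MEG01 6534 and 1068, those against MOLT 4164 and 979, and those against THP1 1925 and 1319. The ratio of 3' to 5' GAPDH signal, a sign of RNA integrity, was 0.96 in log2 in U937 under DMSO, 0.70 and 0.68 at 12 h and 24 h of Tan IIA, 1.45 in THP1, 0.87 in HL60, 0.20 in MEG01 and 0.01 in MOLT.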

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

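Both tests of the shared response at 12 h and 24 h in this part were chosen after the result was seen, and the scaling on poly-A spikes was not planned.

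Under Tan IIA, 34 genes differed from DMSO at least 2-fold in the same direction at 12 h and 24 h, from the chemokine genes CCL2 and CXCL8 to ARRDC3 and TXNIP. Noise of the treated arrays is argued against by the comparison between them, where 9 genes passed 2-fold against 49 between 12 h and DMSO. That comparison does not use the DMSO array and so says nothing about its noise. A DMSO array or culture unlike other untreated U937 cells stays open: over the genes called at 12 h the median further step away from DMSO by 24 h was 0.025, against a median change of 1.17 at 12 h. The design cannot separate this from the effect of Tan IIA, because every comparison with untreated U937 cells rests on 1 array whose time in DMSO was not given. A response to Tan IIA may therefore be read from these genes as a hypothesis that a second set of untreated cultures would test.

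In 4 of the genes named between the times the change from DMSO had opposite directions at 12 h and 24 h, by over 0.40 in log2 each time, and this difference was not tested. ANKDD1A was at −0.55 and 0.61 (24 h minus 12 h 1.17), LINC01119 at −0.72 and 0.51 (1.23), PHKA1 at 0.73 and −0.43 (−1.17) and ZNF765 at 0.76 and −0.54 (−1.30). Further probe sets under the filter showed no reversal, with ZNF765 at −0.91 and −0.50 and PHKA1 at −0.25 and −0.11. With values under the filter set to it, PHKA1 differed by −0.38 between the times, and it was not counted at 24 h against DMSO. Outside the named genes, GZMA of the natural killer cell list, picked after its values were seen, was at 0.46 and −0.45.

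Among the control probe sets, which no comparison used, the 5' end of 28S ribosomal RNA read 0.55 higher at 12 h and 0.87 higher at 24 h than under DMSO, and its middle read 0.60 and 0.76 higher, against a highest change of 0.41 and 0.43 in any poly-A spike. The 3' end of 28S was at 0.03 and −0.05, and the 3 probe sets of 18S ribosomal RNA lay between 0.02 and 0.09 at 12 h and between 0.07 and 0.28 at 24 h.

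Probe sets with no gene listed, also outside the comparisons, held 2-fold differences from DMSO: 4 of 3814 were higher and 14 lower at 12 h, and 15 of 3788 were higher and 30 lower at 24 h.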

How the results depend on the processing

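The poly-A scalings, the restriction to genes with agreeing probe sets and the setting of values under the filter to the filter were chosen after seeing the data; the other settings were planned. No paired analysis was possible because each condition had 1 array and nothing links arrays in pairs. Leaving out _x_at probe sets, centring and cyclic loess kept every count within 1.5 times its value, as did agreeing probe sets alone for 7 of the 8 counts run and leaving out the MEG01, MOLT or THP1 line. Of 102 list medians in U937, 84 moved by less than their spread with centring and 90 with cyclic loess; of 170 between lines, 168 and 160. With the mean of all probe sets it was 83 and 150, without _x_at probe sets 93 and 163, without a filter 97 and 153, with values under the filter set to it 102 and 153, and under the poly-A scalings 7 and 58 (spike median) and 23 and 59 (spike mean). All 75 named values did so without a filter, with centring and with cyclic loess, 48 of 64 with the mean of all probe sets, 70 of 74 without _x_at probe sets (CXCL8 became −1.49 at 12 h and −1.68 at 24 h, and CYP3A4 0.31 at 12 h and −0.31 between the times), 58 of 75 with values under the filter set to it, 47 of 75 and 19 of 75 under the poly-A scalings, and no value past 2-fold changed sign. Of the smaller ones, BCL2 and CYP3A4 at 12 h changed sign under both poly-A scalings, CDKN1A at 12 h under the spike mean, BCL2 at both times with the mean of all probe sets, and CYP3A4 at 24 h without _x_at probe sets. Signal near background limits genes under the filter: in the list not expressed in blood cells, the 95th percentile of values was 7.09, above the filter of 5.45, so that 9 of 20 named genes at 12 h, 6 of 20 at 24 h and 8 of 10 between the times, ARRDC3 at 12 h and MMP1 among them, stayed under it on both arrays. Counts that moved by more than 1.5 times are given as higher then lower; the cause was not tested, except that stricter filters and looser thresholds change how many genes can count.

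With the mean of all probe sets, 24 h against 12 h gave 2 and 1 genes, the overlap of both times 10 and 11, the covariance was 0.0543, and 7 lists lay outside the 1st to 99th percentile for 24 h against 12 h. Without a filter, 10 genes were lower at 24 h than at 12 h and the covariance was 0.0496. With values under the filter set to it, 2 genes were higher at 24 h than at 12 h and the covariance was 0.0621. With agreeing probe sets alone, 2 genes were lower at 24 h than at 12 h. The 75th percentile filter gave 12 and 14 genes at 12 h, 37 and 18 at 24 h, 0 and 3 between the times, and 10 and 9 shared. The background filter gave 13 and 17 at 12 h, 23 lower at 24 h, 0 higher between the times, and 10 and 10 shared. At 1.5-fold there were 179 and 280 at 12 h, 474 and 326 at 24 h, 73 and 53 between the times, 138 and 163 shared, 2466 and 1929 against HL60, 3546 higher against MEG01, 3116 and 2952 against MOLT, 2732 and 2636 against THP1, and 661 and 428 set apart in U937. Without the HL60 line, 415 and 373 genes were set apart in U937.

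Scaled on the median of the poly-A spikes, there were 14 and 78 at 12 h, 23 and 147 at 24 h, 2 and 9 between the times, 8 and 52 shared, 2446 and 569 against HL60, 6534 and 1068 against MEG01, 4164 and 979 against MOLT, and 688 and 118 set apart. Scaled on their mean, there were 8 and 118, 26 and 123, 5 and 56 shared, 2523 and 558 against HL60, 6388 and 1076 against MEG01, 4300 and 965 against MOLT, and 729 and 116 set apart.

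Of all 102 list medians in U937, 42 changed sign under the spike median and 36 under the spike mean, and of the 170 between lines 42 and 41. Among those outside the 1st to 99th percentile on the deposited scale, the ones that did so under the spike median were, at 12 h, NRF2 targets (−0.088), lysosome (−0.039) and receptors (−0.077), and at 24 h, ATF4 (−0.007), mitosis (−0.026), oxidative phosphorylation (−0.18), lysosome (−0.13) and autophagy (−0.022). Under the spike mean they were, at 12 h, NRF2 targets (−0.15), ATF4 (−0.003), mitosis (−0.015), CDK inhibitors and D cyclins (−0.049), lysosome (−0.105) and receptors (−0.14), at 24 h oxidative phosphorylation (−0.13) and lysosome (−0.077), and ATF4 between the times (0.012). Without _x_at probe sets, ATF4 between the times was 0.00. Between lines, also among those outside that range, ATF4 in MEG01 was −0.28 and −0.24 by spike median and mean, oxidative phosphorylation in MEG01 −0.34 and −0.31, and CDK inhibitors and D cyclins in U937 0.21 and 0.23.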

Other observations

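Of the tests in this part, those of array scaling and of dividing cells were chosen after the result was seen, whereas the tests on ribosome assembly genes, chaperones and amino acid genes outside the fixed lists were set out beforehand.

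Genes that serve protein folding in the endoplasmic reticulum were lower at 24 h of Tan IIA. In 7 chaperones and cofactors outside the fixed lists, the median change from DMSO was 0.00 at 12 h and −0.53 at 24 h, when all 7 were below 0. MANF was at −0.79, CRELD2 at −0.71 and the hypoxia-induced chaperone gene HYOU1 at −0.59. On the deposited scale, a list made mainly of genes that charge transfer RNAs and make or carry amino acids was higher. It also held other genes, such as the lipoprotein receptor gene VLDLR. In 18 counted genes the median was 0.32 at 12 h and 0.26 at 24 h. Scaling on the median of the poly-A spikes moved the median of all counted genes to −0.26 at 24 h, a shift about as large as this list median. At 24 h, 6 of the 18 were below 0, SLC1A5 at −0.50, ALDH18A1 at −0.49 and PYCR1 at −0.27 among them. On the higher side, the cystathionine lyase gene CTH was at 1.01, and the synthetase genes AARS1, SARS1 and WARS1 were at 0.65, 0.63 and 0.60. Values of single genes in this part were picked after they were seen.

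Genes of the MYC and ribosome biogenesis list were lower in treated U937 cells, with a median of −0.42 at 24 h. Array scaling is argued against, since it would move other genes of the same expression level alike, whereas the median lay at percentile 0.0 of random lists matched on expression, as deposited and after cyclic loess. Shifts of a whole array leave this percentile as it is and so test nothing here. The mitotic genes, whose median lay at percentile 100 of matched random lists, argue against a loss of mitotic transcripts relative to other genes. They cannot decide whether fewer cells divided, since cells held before or in mitosis can also carry these transcripts. At 24 h their median was −0.026 when scaled on the median of the poly-A spikes. Of 31 G1/S genes, 25 were below 0, with a median at percentile 1.07, inside the range of random lists. In 23 counted genes out of 24 others chosen as ribosome assembly genes, the median was −0.52, at percentile 0.0. All 23 were below 0, among them RRP7A (−0.70), PUS7 (−0.69) and WDR3 (−0.66). A lower output of the ribosome assembly program as a whole, along with MYC, is consistent with these values as a hypothesis. This hypothesis covers the genes of these lists only, and not ribosomal RNA. Not all of them encode assembly factors. The fixed list also holds MYC and the transferrin receptor gene TFRC. Those chosen later include the folate carrier gene SLC19A1 (−0.55) and the importin gene IPO4 (−0.55). The ribosomal RNA precursor RNA45SN5 read higher, at 1.11 and 1.99 on its 2 probe sets at 24 h. The 5' end and middle of 28S ribosomal RNA read 0.87 and 0.76 higher, although its 3' end was at −0.05 and 18S ribosomal RNA at 0.28 or less. Whether these readings follow the output of ribosomal RNA was not tested, so they decide nothing about it. The unrepeated DMSO culture stays open for this hypothesis as for the shared response. RNA integrity was not tested as a source. The log2 ratio of 3' to 5' signal was 0.96 under DMSO against 0.70 and 0.68 at 12 h and 24 h for GAPDH. For ACTB it was 0.88 against 0.71 and 0.775.

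ATF4 targets were higher in treated U937 cells, with DDIT4, SESN2, DDIT3 and ATF3 past 2-fold at 24 h. Stress of the endoplasmic reticulum that raises chaperones is argued against at 24 h, when the 7 further chaperones lay at percentile 0.02. At 12 h, when the ATF4 list was already higher, they lay at percentile 65.57 and decide nothing. Stress that reaches ATF4 targets without raising these chaperones cannot be excluded by them at either time. The amino acid response arm of ATF4 stays a candidate explanation. Of its genes, 19 were tested and 18 counted, with a median at percentile 99.98 and 12 of the 18 above 0. These genes are ATF4 targets themselves, so the test cannot tell this arm from another source of higher ATF4 output. These percentiles are relative to other genes, and on the scale of the poly-A spike median the ATF4 list stood at −0.01 at 24 h. The unrepeated DMSO culture stays open here too.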
